A study of Mus musculus with 9 samples.

How the data were processed

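The samples are regulatory T cells sorted from mice, taken without stimulation, with total RNA amplified by a SMARTer kit and sequenced on Ion Proton libraries, per the labels. The labels give genotype and a number for each sample, and do not say what the numbers mean or whether samples came from separate animals, so p-values measure the spread between these samples, which may be technical. The submitters' processing notes name STAR, BWA, edgeR and the mouse build mm9, with no versions or roles, and the annotation and read counter were not given in the sources used here.

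The authors deposited raw read counts per gene symbol, a table of log2 values and a table of 1 signed value per gene. Among the rows of counts, 5 are summaries of the read counter and were kept out of library sizes and tests. Reads assigned to genes made up 22.0 to 23.7% of each column, and reads on no feature 47.7 to 54.3%. The authors' log2 values are, within each column, log2 counts minus a constant for genes above 1000 reads, and not at low counts, where a count of 0 has the value -8.244 in every column; how the authors set the scaling was not given. The authors' deposited table of signed values has no named groups, direction or log base and was used only for description: of 11923 genes with 0 counts in all 9 columns, 2250 have another value than 0 there.

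Per table, 2 of the 9 value columns share the number 407, which the labels give to a WT and to a CNS2KO sample, and the 2 columns hold identical values in every row. These 2 columns per table were not used, because their genotype could not be told. The planned comparison of 6 WT with 3 CNS2KO samples was therefore made on 5 and 2. The lowest chi-square per degree of freedom between counts of a pair of used libraries was 31.6, so no used pair agreed within sampling noise.

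Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr, libraries scaled by TMM, and the genotypes compared by the two-sided quasi-likelihood test with Benjamini-Hochberg adjustment at an FDR of 0.05. Standard errors are the fold change over the root of the F statistic, and 95% intervals use the test's degrees of freedom. CPM values are TMM-scaled. A floor of 3 counts corresponds to 0.142 to 0.182 CPM per library; floors cover counting error only, since reads carry no molecular identifiers. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), with an estimated correlation and with fry as alternatives. List percentiles come from 10000 random lists matched on 20 expression bins. Gene order around Foxp3 came from a GRCm38.p6 gene table, which placed 94.4% of tested genes by name; no coordinates are given, since the build differs.

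The tests were checked on simulated counts with 200 changed genes. With no change simulated, 1 of 13840 genes and 0 of 19 lists were called. Each gene was simulated independently, so the count of lists does not check camera where members of a list vary together. Tests, alternatives, lists and the rule for named genes were fixed before the data were examined. The rule named Foxp3; up to 12 genes past the threshold per direction, or, where fewer than 5 passed, the 5 with the smallest p, leaving out predicted and clone names; up to 4 passing members of each list, or otherwise the 2 most highly expressed; and 5 sex-linked and 3 T cell genes. Some genes that the rule names are not reported here. Alternatives were relative log expression and upper-quartile scaling, DESeq2 1.42.0, edgeR's exact test, limma-voom, no filter on low counts, a filter at 10 CPM in 3 libraries, WT numbers of 3 digits only, a term for libraries 1032 and 1037, 1 surrogate variable from sva 3.50.0, thinned counts, an FDR of 0.1, an added fold change limit, and each library left out. Where a CNS2KO library was left out, only the WT libraries gave the spread. A limma fit of the authors' log2 values and a ribosomal list less the S6 kinases and Rps19bp1 were chosen after seeing the data.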

Results

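RNA from resting regulatory T cells, the CD4 T cells that express the transcription factor Foxp3, was sequenced from wild-type mice with a green fluorescent Foxp3 reporter (WT) and from mice that carry the reporter and lack CNS2, a conserved noncoding element inside the Foxp3 gene (CNS2KO). The labels list 6 WT and 3 CNS2KO samples, and 5 WT and 2 CNS2KO libraries could be compared. Reads on genes ranged from 16557424 in WT 402 to 21836578 in CNS2KO 399. Pearson's r of log2 CPM across genes ranged from 0.879 to 0.949 over the 10 pairs of WT libraries and was 0.913 for the CNS2KO pair. The highest of all pairs, 0.977, joined WT 398 and CNS2KO 408. Genes within a library are not independent replicates.

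The first question was whether Foxp3 transcript levels differed in resting cells without CNS2. Foxp3 stood at 488 ± 78.9 CPM in WT (SD, n = 5) and at 452 ± 15.9 CPM in CNS2KO (SD, n = 2). The log2 fold change was -0.11 (SE 0.18, 95% interval -0.50 to 0.28), and both CNS2KO libraries lay inside the WT range of 410 to 607 CPM. Il2ra, the high-affinity IL-2 receptor chain, stood at 1830 ± 237 CPM in WT and 1790 ± 58.7 CPM in CNS2KO, and Cd4 at 650 ± 87.4 and 570 ± 48.3 CPM. The T cell receptor component Cd3e (log2 fold change -0.12) and the leukocyte phosphatase Ptprc (0.06) also differed by less than the spread between libraries. The two-sided exact permutation test of Foxp3 gave p = 0.667 over 21 assignments, of which the smallest possible p is 0.048. CNS2 is noncoding, so Foxp3 counts do not check the genotype labels. With WT numbers of 3 digits only, the log2 fold change of Foxp3 was -0.19.

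**Figure D1:**
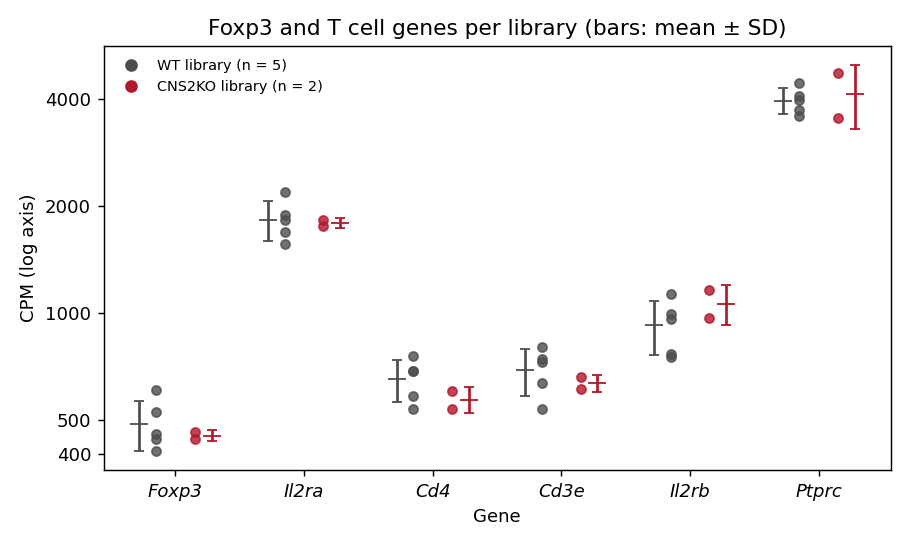
CPM (log axis) of Foxp3, Il2ra, Cd4, Cd3e, Il2rb and Ptprc in each WT library (grey) and CNS2KO library (red), with bars for the mean and SD of each genotype. Foxp3 ranged from 410 to 607 CPM in WT and from 441 to 464 CPM in CNS2KO.

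The transcript 4930524L23Rik, which lies directly before Foxp3 and is named Flicr in the GRCm38.p6 gene table, was picked out after its values were seen. It stood at 35.2 ± 4.41 CPM in WT (SD, n = 5) and 15.4 ± 5.75 CPM in CNS2KO (SD, n = 2). The log2 fold change was -1.20 (SE 0.30, 95% interval -1.84 to -0.55), and both CNS2KO libraries (11.3 and 19.4 CPM) lay below the lowest WT library (27.7 CPM). The exact permutation test gave p = 0.048, the smallest that 21 assignments allow, and the gene ranked 6 of 14424 by edgeR's unadjusted p of 0.00173 (adjusted p = 1). Both CNS2KO libraries lay below every WT library in 432 genes, 3% of those tested, where chance gives 4.76%. Strand use in counting was not given in the sources used here, and reads from overlapping transcripts at this locus could not be separated.

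The second question was which other transcripts differed between the genotypes. The 5 genes with the smallest p in each direction, named by the fixed rule, did not pass. Chordc1, a co-chaperone of Hsp90, stood at 176 ± 18.0 CPM in WT and 301 ± 17.4 in CNS2KO (log2 fold change 0.78, SE 0.16). The interferon-inducible GTPases Iigp1 (0.78) and Tgtp1 (0.70), Ly6k (2.19) and the mitochondrial ribosomal protein gene Mrpl32 (0.88) were the others of positive sign. The lymphoid transcription factor Ikzf3 stood at 188 ± 18.5 CPM in WT and 115 ± 29.9 in CNS2KO (log2 fold change -0.71, SE 0.20), and Arid5b (-0.69), Ppm1l (-0.99), Sepsecs (-0.80) and the choline kinase gene Chka (-2.78) were the others of negative sign. Without CNS2KO 399, Ly6k stood at 0.75, Ikzf3 at -0.46, Ppm1l at -0.64 and Chka at -1.83, and without CNS2KO 408, Iigp1 at 0.53, Ikzf3 at -1.01, Ppm1l at -1.46 and Chka at -6.46. Chka had 2 reads in CNS2KO 399, under the floor of 3 counts, and limma-voom gave it -3.98. edgeR's quasi-likelihood test called 0 of 14424 genes at an FDR of 0.05, with 361 genes at an unadjusted p under 0.05 (222 higher and 139 lower in CNS2KO), where chance gives 721. Without CNS2KO 408, 0 genes passed (smallest adjusted p = 0.052) and 1676 of 15797 had an unadjusted p under 0.05. The other tools also called 0 genes at an FDR of 0.05: DESeq2 had 496 at an unadjusted p under 0.05, edgeR's exact test 403, limma-voom 614 and limma on the authors' log2 values 563. The smallest adjusted p was 0.076 by DESeq2, 0.058 by edgeR's exact test and 0.99 by limma-voom. The first 2 lie under the looser FDR of 0.1, which was applied to the quasi-likelihood test only. With WT numbers of 3 digits only, 0 genes passed and 271 had an unadjusted p under 0.05. In simulated counts for this comparison, the test called 24 of 100 genes changed 2-fold and 67 of 100 changed 4-fold, and 43 of 43 changed 4-fold above a log2 CPM of 5. Genes were simulated independently and the lowest expressed were not changed, so these shares may not hold for the real counts.

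Of 19 gene lists fixed in advance, 4 passed camera with a preset correlation, and 0 passed with an estimated one. The list of Rpl and Rps gene symbols had positive fold changes in 77 of 88 (median log2 0.29), with Rpl4 at 0.25 and Rpl3 at 0.13. The list's adjusted p was 5.2e-08, and adjusted p = 0.77 with an estimated correlation. Its symbols take in 9 genes that are not ribosomal proteins, the S6 kinases and Rps19bp1; less these, 73 of 79 were positive (median 0.30, adjusted p = 3.7e-10, and adjusted p = 0.80 with an estimated correlation), a count added after seeing the data. Interferon response genes had positive fold changes in 18 of 18 (median 0.52), with the guanylate-binding protein Gbp2 at 0.54. The list's adjusted p was 0.00038, and adjusted p = 0.77 with an estimated correlation. No member of either list passed over all genes or adjusted over the list alone. Library means of the interferon list, against the WT mean on the log2 scale, were 0.96 in CNS2KO 408, 0.00 in CNS2KO 399 and 0.51 in WT 1037. Without CNS2KO 408 the interferon median was -0.12 (adjusted p = 0.98), and without CNS2KO 399 the median of the 88 was 0.09 (adjusted p = 0.63), with Rpl4 at -0.03 and Rpl3 at -0.28.

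Genes of effector regulatory T cells had negative fold changes in 24 of 30 (median -0.36). The list mean against the WT mean, on the log2 scale, was -0.82 in CNS2KO 399, below every WT library. In CNS2KO 408 it was -0.26, inside the WT range of -0.47 (WT 402) to 0.45 (WT 1037). The costimulatory receptor Icos stood at -0.26 and the transcription factor Gata3 at 0.09, and the chemokine receptor Ccr8 at -0.91 and S100a6 at -0.88, both picked out after their values were seen. The list's adjusted p was 0.00092 by camera, and adjusted p = 0.77 with an estimated correlation. In the list 0 members passed over all genes or adjusted over the list alone, and 3 had an unadjusted p under 0.05. With WT numbers of 3 digits only, the median was -0.18 (adjusted p = 0.29), and with a term for libraries 1032 and 1037 it was -0.18 (adjusted p = 0.34).

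Erythroid transcripts, which mark red blood cells and not T cells, had positive fold changes in 6 of 6 measured members (median 2.13). The beta globin transcript Hbb-b1 stood at 8.10 ± 4.39 CPM in WT (SD, n = 5) and 45.2 ± 47.0 CPM in CNS2KO (SD, n = 2), with 78.4 CPM in CNS2KO 399 and 11.9 CPM in CNS2KO 408. The alpha globin transcript Hba-a1 stood at 4.67 ± 2.47 and 18.2 ± 15.1 CPM. In this list 0 members passed over all genes and 3 passed adjusted over the list alone. The list's adjusted p was 0.00033 by camera, and adjusted p = 0.66 with an estimated correlation. Without CNS2KO 399 the median was 0.62 (adjusted p = 0.40). The globin genes are near-identical copies, and the split of reads among them is uncertain.

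**Figure D2:**
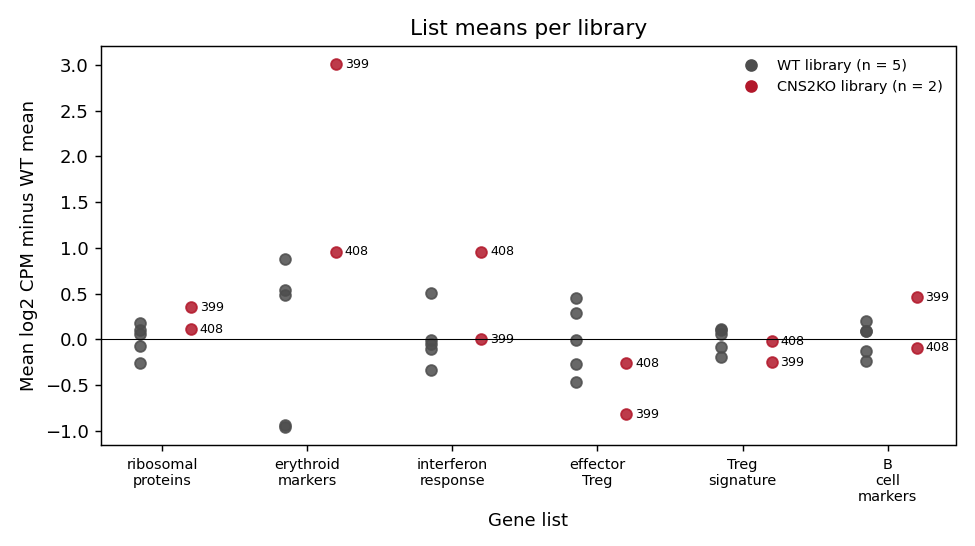
Mean over list members of log2 CPM minus the WT mean, for 6 gene lists, in each WT library (grey) and CNS2KO library (red, numbered). CNS2KO 399 lay at 3.01 for erythroid markers and CNS2KO 408 at 0.96 for the interferon response.

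The other 15 lists did not pass camera. The regulatory T cell signature had 12 positive and 18 negative members (median -0.03), genes low in regulatory T cells a median of -0.18, with Il7r at -0.23 and Lef1 at -0.18, and resting regulatory T cell genes -0.21, with S1pr1 at -0.34. Medians were 0.03 for IL-2 and STAT5 response genes, -0.02 for helper T cell cytokines and regulators (Cxcr5 0.18), 0.00 for immediate T cell receptor response genes (Cd69 0.23, Nfkbia 0.12) and 0.01 for cell cycle genes (Pcna 0.18, Mcm3 -0.17). DNA methylation enzymes had a median of -0.14 (Dnmt1 -0.51, Tet3 -0.14), Foxp3 regulators 0.05 (Ets1 0.02, Foxo1 -0.25), and the listed X-linked neighbours of Foxp3 -0.28 (Plp2 -0.38, Ccdc22 -0.12). Without CNS2KO 399 the neighbour list's median was -0.70, and without CNS2KO 408 it was -0.07, in fits where only the WT libraries gave the spread. With all libraries the neighbour list had an adjusted p = 0.10 by camera, and adjusted p = 0.66 with an estimated correlation. Without CNS2KO 399 and without CNS2KO 408, Dnmt1 stood at -0.04 and -1.20, Tet3 at 0.23 and -0.64, and the methylation list's median at 0.04 and -0.58. The signs of Nfkbia, Ets1 and Ccdc22 and of the cell cycle, immediate response and Foxp3 regulator medians also turned between these fits. In these lists 0 members passed adjusted over the list alone.

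Markers of other cells also did not pass. B cell markers had a median of 0.05 (Ighm -0.10, Cd74 0.19), myeloid markers 0.17 (Cst3 0.15, Csf1r -0.32), CD8 and NK cell markers 0.20 (Cd8b1 -0.54, Prf1 0.28) and mitochondrial transcripts -0.03 (mt-Rnr2 0.04, mt-Co1 0.09). Heat shock and dissociation stress genes had a median of 0.25 and a mean of -0.12, with Hspa8 at 0.48 and Zfp36 at -0.23, and 1 member, the chaperone Hsp90aa1 (0.71), passed adjusted over the list alone. Without CNS2KO 408 the heat shock list's median was 0.29, and without CNS2KO 399 it was -0.13, in fits where only the WT libraries gave the spread. With all libraries the heat shock list had an adjusted p = 0.22 by camera, and adjusted p = 0.85 with an estimated correlation. Signs that turned between the fits without CNS2KO 399 and without CNS2KO 408 included those of Hspa8, Zfp36, Cd74, Cst3 and Prf1. The B cell, myeloid, CD8 and NK and mitochondrial medians also changed sign. In the B cell, myeloid, CD8 and NK and mitochondrial lists 0 members passed adjusted over the list alone. Fry's test for change in either direction gave the B cell list an adjusted p of 0.015. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were read in all 7 libraries, at WT means of 290, 277, 68.5 and 94.9 CPM, and Xist had at most 5 reads in any library.

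**Figure D3:**
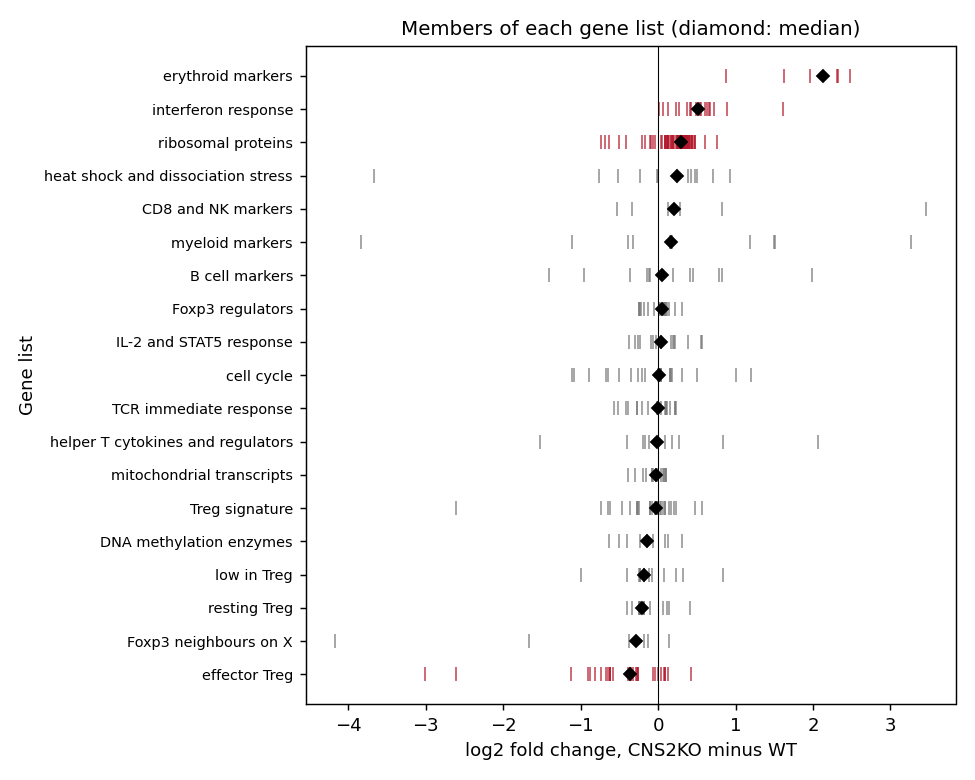
Log2 fold change (CNS2KO minus WT) of each measured member of 19 gene lists, with a diamond at each list's median. Ticks are red for the 4 lists past camera with a preset correlation, and the medians ran from -0.36 for effector regulatory T cell genes to 2.13 for erythroid markers.

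The authors' deposited table gives 1 signed value per gene and does not name the groups, the direction or the log base. In the authors' deposited table the regulatory T cell signature had 22 positive and 8 negative values (median 0.25) and the effector genes 22 positive and 8 negative (median 0.61), each above nearly all of 10000 random lists matched on expression. Random lists do not keep together genes that vary together, so these ranks and the percentiles below do not measure chance. In the authors' deposited table genes low in regulatory T cells had a median of -0.16 (percentile 0.7), erythroid markers -1.39 and cell cycle genes -0.20 (percentile 1). In the authors' deposited table the Rpl and Rps list had 78 positive values of 88 (median 0.13, percentile 100). That is the sign of its CNS2KO minus WT median, while the erythroid and effector lists had the opposite sign to theirs. Interferon response genes had 9 positive and 9 negative values in the authors' deposited table (median -0.01, percentile 21.3). In the authors' deposited table Foxp3 had the value 0.61, 4930524L23Rik 1.05, Ppp1r3f 0.57, Ccdc22 0.68 and Plp2 0.69. Across the tested genes these values and the CNS2KO minus WT log2 fold changes had a Pearson's r of -0.09 and a Spearman's rho of -0.01, and 50.3% had the same sign, with genes not being independent replicates.

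**Figure D4:**
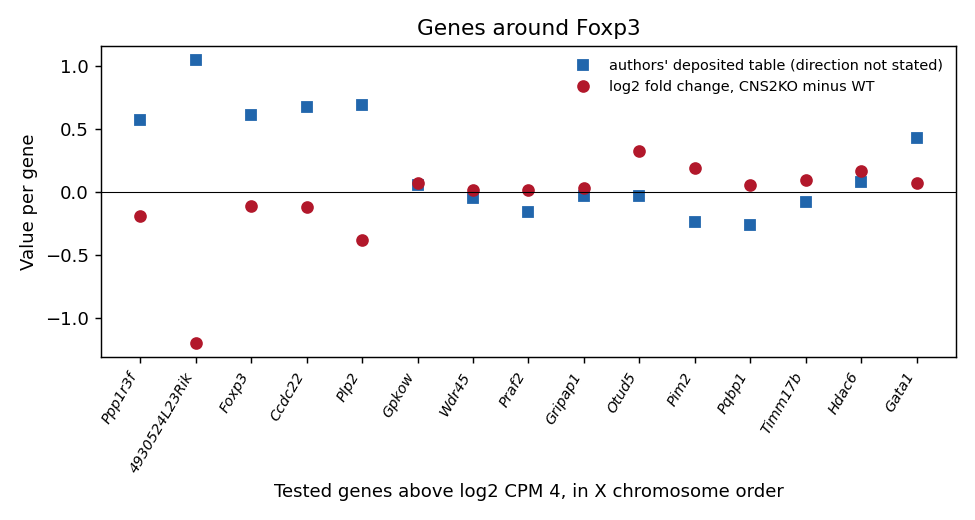
Values in the authors' deposited table (blue squares, direction not stated) and log2 fold changes of CNS2KO minus WT (red circles) for tested genes above a log2 CPM of 4 from Ppp1r3f on, in X chromosome order. The 5 genes from Ppp1r3f to Plp2 had values from 0.57 to 1.05 in the authors' deposited table and log2 fold changes from -1.20 to -0.11.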

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

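In 79 checks of 5 WT values each, 4 had 1 library far from the others, and chance gives about 1 in 20. All 4 were the high values of WT 1037: 86.4 CPM for Mrpl32, against 59.5 in the next library, 138 CPM for Pcna (104), 1310 CPM for Ighm (1060) and 0.292 CPM for Xist (0.0545), the last from 5 reads. The tests of red blood cell RNA and of a difference shared by both CNS2KO libraries, the X chromosome test and the test of the table's origin were chosen after the results were seen.

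Erythroid transcripts were higher in the CNS2KO libraries. Of the 21 splits of the 7 libraries into 5 and 2, 1, the real one, gave the list a camera p as small as 3.5e-05, and the smallest in the other splits was 6.4e-05, for WT 405 with CNS2KO 399. The value rested on CNS2KO 399. In 0 of the 2 most abundant transcripts did both CNS2KO libraries lie above every WT library, with CNS2KO 408 close below the WT maximum. By the list mean against the WT mean, on the log2 scale, both did, at 3.01 in CNS2KO 399 and 0.96 in CNS2KO 408. CNS2KO 408 lay only just above WT 405, at 0.88. A genotype difference shared by both therefore stays open. RNA of red blood cells carried into a sorted sample may also account for it: Spearman's rho of Hbb-b1 and Hba-a1 over 7 libraries was 0.46 (exact permutation p = 0.30, adjusted p = 0.30) and Pearson's r of log2 CPM 0.97 (exact permutation p = 0.023, adjusted p = 0.047), but r was 0.01 without CNS2KO 399 and WT 1037. These explanations cannot be told apart with 2 CNS2KO libraries.

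Interferon response genes were higher in the 2 CNS2KO libraries on average. In 2 of the 21 splits the list's camera p was as small as the real 6.0e-05, the smallest elsewhere being 2.7e-16 for WT 1037 with CNS2KO 408, so chance is not excluded. The list mean of CNS2KO 399 minus that of the highest WT library was -0.51 on the log2 scale, against a WT SD of 0.31, which argues against a shift shared by both CNS2KO libraries. A difference in scaling stays open: the median was 0.51 under both other scalings, but these moved the median of all genes by at most 0.007, so they test nothing. What sets CNS2KO 408 and WT 1037 apart from the rest stays open.

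Foxp3 and its neighbours had like positive values in the authors' deposited table. Of 7115 runs of 4 neighbouring genes above a log2 CPM of 4, 2 (0.028%) lay as far from 0 on one side. Both were the runs from Ppp1r3f to Plp2 themselves, which were picked after their values were seen and set the cutoff. Their rarity therefore does not measure chance. That no other run reached the cutoff argues against a general property of neighbours. The median over 251 X-linked genes was 0.07, which argues against a shift of the whole chromosome. No tested gene placed above this expression limit lay before Ppp1r3f on X, so that side was not examined. The table was not made from the deposited count columns alone, since 2250 genes without reads have a value. A strain difference linked to the targeted locus and an effect of the element on its neighbours are candidate explanations that were not tested, and the table does not name its groups.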

How the results depend on the processing

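Foxp3 stayed on the same side of the threshold under all alternatives run, with log2 fold changes from -0.19 to -0.02. The count of genes called stayed at 0 except with no filter on low counts, where it was 8 (7 higher, 1 lower), of which 4 had over 10 times the reads in CNS2KO 399 of any other library; Hbb-b1 and Ly6k were the named genes among them. All 21 splits gave as many genes as the real 0, the highest other being 0, so the count says nothing of chance, and 10 of the 21 gave as many lists as the real 4, the highest other being 6. For the ribosomal and effector lists, 3 of the 21 gave a camera p as small as the real 2.7e-09 and 0.00019, the smallest others being 1.5e-14 and 1.7e-09, so chance is not excluded. The count of lists was 0 by camera with an estimated correlation and 0 by fry's directional test; lists were not tested with DESeq2 or edgeR's exact test. The B cell list turned to a median of -0.22 without CNS2KO 399, and with 1 library left out its median ranged from -0.22 to 0.34. With all libraries the B cell list had a camera adjusted p of 0.99, with a preset and with an estimated correlation. The correlation with the authors' deposited table was -0.02 with limma-voom, 0.02 with no filter, 0.00 at 10 CPM, -0.03 with WT numbers of 3 digits only, -0.02 with the term for libraries 1032 and 1037, -0.04 with 1 surrogate variable and -0.01 on the authors' log2 values, a fit chosen after seeing the data; with each library left out it ranged from -0.12 to -0.06. For these changes the cause was not tested. A value of a named gene was counted as the same if it stayed short of the FDR threshold and moved by no more than 1 SE of the main fit. A value could therefore change sign and still count as the same. By this rule 615 of 621 values were the same under other settings, and 321 of 364 with 1 library left out. All settings reuse the same libraries, so these counts do not show that the values would repeat in others. Genes under about 0.182 CPM lie at the depth limit. No paired analysis was possible because the genotypes share only the number 407, whose columns could not be assigned.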

Other observations

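The test in this part was chosen after the result was seen. The signs in the authors' deposited table were set against those of the CNS2KO minus WT log2 fold change, under the hypothesis that the table is oriented the other way. Over 20 combinations of an expression minimum and a minimum absolute value, all of which were looked at, the share of opposite signs ran from 43.9% to 85%, the highest over 20 genes, and it was 75.8% over 66 genes and 48.5% over 7293 genes. In 9 of the 21 splits of the libraries the most extreme combination lay as far from 50% as the real 35 percentage points, the highest other being 50, so chance is not excluded and the high shares rest on the choice of combination. The combinations with the fewest genes, 2 and 7, dominate this test, which makes it a weak one. The direction of the table stays unknown.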
